A study of Homo sapiens with 4 samples.

How the data were processed

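RNA was sequenced from NK-92, a human natural killer (NK) cell line that grows in medium with interleukin 2 (IL-2). The wild-type line (WT) was compared with an edited line, called ΔOGT-ISS, in which CRISPR-Cas9 removed an intronic splicing silencer of OGT. OGT encodes the enzyme that attaches O-GlcNAc, a single sugar, to proteins inside the cell. Each line had 1 library with IL-2 given 48 hours before RNA extraction and 1 with IL-2 given 24 hours before it, so that 4 libraries fill the 4 combinations of line and time. In the numbering used here, replicate 1 of each line is the 48 h library and replicate 2 the 24 h library. The library titles mention IL-2 only for the 24 h libraries, while the sample labels give IL-2 to all 4. The times used here follow the labels.

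Total RNA was depleted of ribosomal RNA with RiboCop and made into libraries with the CORALL RNA-seq V2 kit, per the labels' protocols. The raw counts are whole numbers of reads per Ensembl gene, deposited without normalization. HISAT2 2.2.0, SAMtools 1.15.1, featureCounts 2.0.1 and genome build hg38 are named, per the submitters' processing notes, with no roles or options. The annotation release, the strand setting and the treatment of multi-mapping reads and of molecular identifiers are not given in the sources used here. Antisense or overlapping genes and near-identical gene copies are therefore uncertain. The FPKM values deposited by the authors equal the count divided by a transcript length in the same table and by the sum of counts. That table lacks 1188 of the 61860 gene identifiers in the count table and lists 3 identifiers more than once. No column belonged to other samples.

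The deposited FPKM table gave symbols for 41013 identifiers and a reference name table for another 1404, which left 19443 without a symbol. Positions came from GENCODE release 29 on GRCh38, which placed 58308 of the identifiers. Counts per library totalled 11305599 for ΔOGT-ISS and 10889986 for WT at 48 h, and 28576566 and 24809269 at 24 h. A count of 0 allows up to 3 counts, which is 0.263, 0.284, 0.103 and 0.122 TMM-normalized CPM in those libraries, and bounds given as at least so many fold use that limit. Intervals on ratios between single libraries are exact conditional binomial 95% intervals. They cover counting error only, as do the limits for a count of 0. For each gene at 2 counts there were 0.973 and 0.932 genes at 1 count in the 48 h libraries, against 1.70 and 1.72 at 24 h, so the bounds at 48 h rest on counting that is not ordinary at its low end.

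The main tests were edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3 on the raw counts, with TMM normalization. Genes were kept by filterByExpr with a minimum count of 10, which left 17492. The model had additive terms for line and IL-2 time and used all 4 libraries. It leaves 1 residual degree of freedom, which also holds any interaction of line with time, and edgeR moderates the spread across genes. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Nothing in the labels says that the libraries came from separate cultures of 1 condition, so the p-values measure only the spread between these libraries, which may be technical. Only 1 edited line was compared with the WT line, so a difference between them cannot be assigned to the edit alone. The line difference at each time rests on 1 library per line. It is given as a log2 ratio of TMM-normalized CPM with a prior count of 2, with no test.

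For 30 gene lists, camera in limma 3.58.1 was run on voom values with the same model and a preset correlation of 0.01. Adjustment was over the 30 lists within each comparison. It was repeated with an estimated correlation and with fry. With 1 residual degree of freedom the estimated correlation comes from the signs of the residuals alone and the test has 1 degree of freedom, so the loss of calls there follows partly from its construction. Members past the gene test were counted over all genes and adjusted over the list alone.

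The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. OGT and OGA were named first. In each comparison the rule then took the 10 largest changes in each direction among genes past the test, with the same sign in both pairs of libraries and a mean of at least 5 CPM. From each list it took up to 4 members past the test, or the largest changes until 2 were named. For the difference between times it took the 5 largest in each direction among genes with at least 10 CPM in 1 library. Pseudogenes, clone-based names and a fixed list of small RNA symbol prefixes were counted but not named. That list did not hold the symbol U2, which the rule therefore took. Some genes that the rule took are not reported here.

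The other settings fixed beforehand were size factors from DESeq2 1.42.0, upper-quartile factors, library sizes without mitochondrial genes and the 10 most abundant genes, no filter beyond 1 count, and at least 5 CPM in 2 libraries. Others were the DESeq2 Wald test, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 2 libraries, a model without the other factor, and leaving out each library. Leaving out a library also meant dropping the other factor, so such a fit mixes line with time. The ratio within each time is the line difference free of that mixing. The remaining library of that group was assumed to vary like the others.

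Chosen after seeing the data were offsets for GC content and transcript length (loess per library, span 0.3, degree 1), removal of the running median of 41 neighbouring genes, protein-coding genes only, and thinning of the 24 h libraries to the depth of the WT 48 h library. Only 1 form of the offsets was run. They remove any difference between libraries that follows GC content or length, a biological one included. The tests were run on simulated counts, with means and a trend of spread taken from these libraries. The simulation behind the values below held no extra spread of single genes around that trend. It also had no interaction of line with time, no trend with GC content and no regional shift. Only genes with a mean of at least 5 CPM were changed. Recovery and false calls may therefore look better than in the real data. Of the genes changed in the simulation, edgeR recovered 56.7% of 67 at 2-fold, 98.5% of 67 at 4-fold and 100% of 66 at 8-fold for the line comparison, with 16367 genes tested and 6 false calls. For the time comparison the shares were 56.7%, 97.0% and 100%, with 16346 genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.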

Results

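Gene expression was measured by total RNA sequencing in NK-92 cells, wild type or with the intronic splicing silencer of OGT deleted. The edit was designed to sustain OGT expression and raise O-GlcNAc, and the libraries address which genes differ between the lines. There were 2 libraries per line, 1 with IL-2 given 48 h and 1 with IL-2 given 24 h before extraction. The 48 h libraries held 10889986 and 11305599 counts and the 24 h libraries 24809269 and 28576566. Library composition differed more between the times than between the lines. Across genes, log2 CPM correlated at 0.943 between the lines at 48 h and 0.979 at 24 h, against 0.903 in WT and 0.911 in ΔOGT-ISS between the times. The signal recognition particle RNA RN7SL1 took 0.394% and 0.426% of the counts at 48 h (ΔOGT-ISS and WT) and 2.76% and 4.39% at 24 h. Mitochondrial ribosomal RNA took 0.358% and 0.187% at 48 h and 0.0162% and 0.0175% at 24 h.

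OGT (ENSG00000147162, chromosome X, 71533083 to 71575897, GRCh38) was counted at 399 CPM in ΔOGT-ISS and 446 CPM in WT at 48 h, a ratio of 0.893 (95% counting interval 0.857 to 0.930). At 24 h it was counted at 384.0 and 449 CPM, a ratio of 0.855 (0.833 to 0.878). The log2 difference over both times was -0.19 (SE 0.16, edgeR adjusted p = 0.862). OGA (ENSG00000198408, chromosome 10, 101784443 to 101818465), which encodes the enzyme that removes O-GlcNAc, had ratios of 0.840 (0.782 to 0.902) at 48 h and 0.869 (0.831 to 0.909) at 24 h. Its log2 difference was -0.23 (SE 0.15, edgeR adjusted p = 0.804). Total OGT counts were thus not higher in the libraries labelled ΔOGT-ISS. Counts per gene do not separate spliced from intron-retaining transcripts, so they do not check the deletion. The hexosamine and O-GlcNAc list as a whole did not pass the test between the lines (0 of 12 members past the edgeR test, camera adjusted p = 0.425).

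**Figure D1:**
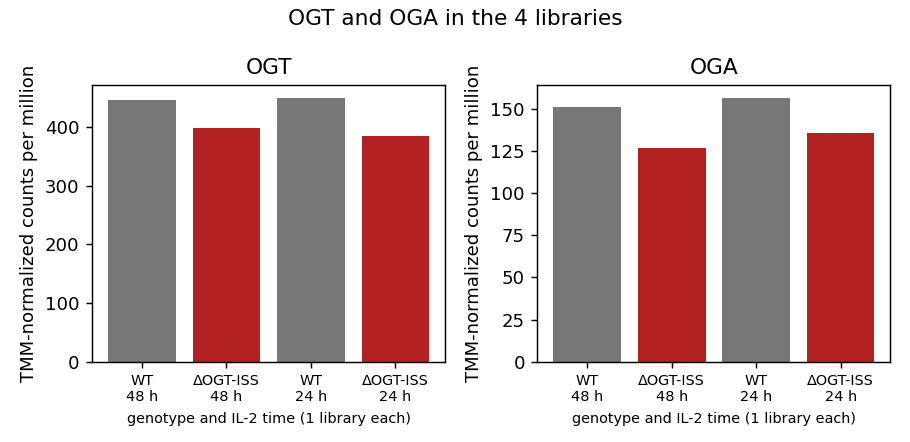
Expression of OGT and OGA in each of the 4 libraries, as TMM-normalized CPM on an axis from 0. OGT lies at 399 and 384.0 CPM in the ΔOGT-ISS libraries and at 446 and 449 CPM in the WT libraries.

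Between the lines, the largest increases in ΔOGT-ISS were in the interferon-induced genes IFI44L and IFI44, in PLOD2, a collagen lysyl hydroxylase, and in NLGN1, a synaptic adhesion molecule. IFI44L (ENSG00000137959) had 990 counts against 0 in WT at 48 h, which is at least 306-fold higher against the limit of 3 counts (the two-sided interval starts at 248), and 121 against 4 counts at 24 h, a ratio of 25.7 (9.78 to 95.8). Its fitted log2 change was 7.66 (SE 0.84, edgeR adjusted p = 0.0142, but 8.37 with DESeq2 adjusted p = 0.125). PLOD2 had 186 against 0 counts at 48 h, at least 57.4-fold higher (interval from 46.2), and 425 against 4 at 24 h. NLGN1 rose by 5.81 log2 units (SE 0.41) and IFI44 by 4.23 (SE 0.60). TNFRSF8, which encodes the receptor CD30, rose 7.44-fold (log2 2.90, SE 0.22, edgeR adjusted p = 0.00544), and the ligand gene HHLA2 rose 6.19-fold. CAVIN4, RUNX1T1, NRXN3 and the DNA methyltransferase DNMT3B rose by 3.67, 2.67, 2.02 and 1.71 log2 units. The NRXN3 ratio was 4.42 (3.49 to 5.64) at 48 h and 3.68 (2.46 to 5.67) at 24 h.

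The largest decrease among the named genes was in CHFR, a mitotic checkpoint ubiquitin ligase, at log2 -5.18 (SE 0.49, edgeR adjusted p = 0.0118). CHI3L1, a secreted chitinase-like protein, fell by 4.78 log2 units (SE 0.47), from 6531 to 483 counts at 48 h and from 2010 to 33 at 24 h. The phosphatase gene PTPN3 had a log2 difference of -4.13 (SE 0.44), with 2 counts in ΔOGT-ISS at 24 h and a ratio there of 0.0354 (0.00417 to 0.135). IL18R1, a subunit of the interleukin 18 receptor, fell by 3.38 log2 units (SE 0.38, edgeR adjusted p = 0.0159). NT5DC3, ZNF423, ATP10A, LIM2 and NFILZ had log2 differences of -4.12, -3.77, -3.17, -3.03 and -2.94. GOLGA8M, at -3.24, belongs to a family of near-identical copies on chromosome 15 and is uncertain.

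In all, edgeR called 81 of 17492 genes between the lines, 26 higher and 55 lower in ΔOGT-ISS, and 1589 passed an unadjusted p of 0.05. All 81 differed at least 2-fold, 76 were protein-coding, and 80 had the same sign at both times. The shared sign follows largely from the model, whose residual is the disagreement between the times, and is not separate evidence that the calls repeat. The count depended on the model: DESeq2 called 303, while limma on FPKM called 0 with either pseudocount (1340 and 1199 unadjusted). Without the IL-2 term edgeR called 0 with all 4 libraries (242 unadjusted). With 3 libraries that term leaves no residual degree of freedom, so the fits that left out 1 library also lacked it, mix line with time and do not show what a single library adds. They gave 0 without ΔOGT-ISS replicate 1, 0 without WT replicate 1, 16 without ΔOGT-ISS replicate 2 and 0 without WT replicate 2 (392, 295, 519 and 589 unadjusted). With the 24 h libraries thinned to the depth of WT at 48 h, a step chosen after seeing the data, it called 44, all among the 81. Of the named genes, IFI44 (4.45, edgeR adjusted p = 0.0587), SLC7A11 (1.25, 0.0638), GZMA (-1.24, 0.0661) and HAVCR2 (-1.38, 0.0710) then ended short of the threshold at about their size in the main test.

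Part of the differences followed chromosome position. Over 299 expressed protein-coding genes of chromosome 15 the median log2 ratio was -0.52 at 48 h and -0.49 at 24 h, and 87.3% and 96.3% of these genes lay below the median of all such genes. Runs of lower ratios covered chromosome 15 from 22838641 to 43802589 and from 55340032 to 101724604, chromosome 10 from 134465 to 45594906 (medians -0.66 and -0.72) and chromosome 7 from 27170591 to 66995601 (-0.53 and -0.46). Over all 423 such genes of chromosome 7 the medians were -0.28 and -0.25, with 71.9% and 85.1% below the median of all such genes. A run on chromosome 20 from 32109506 to 36593950, which holds DNMT3B, lay higher, at 0.97 and 0.78 over 41 genes. These 5 regions held 951 tested genes (5.44%) and 23 of the 81 called genes (28.4%), each with the sign of its region. The regions were picked as blocks of about 40 genes with medians past 0.3 log2 units at both times. They thus rest on the same ratios as the calls, so the larger share and the shared sign follow in part from that choice. With the regional median removed, a step chosen after seeing the data, edgeR called 38 genes, of which 36 were among the 81. This fall is not the regional share of the calls: of the 45 lost, 24 lay outside the 5 regions, where their median size went only from 1.44 to 1.38 log2 units, and 21 inside, where it went from 1.47 to 0.86. DNMT3B then stood at 0.94 (edgeR adjusted p = 0.195) and ATP10A, on chromosome 15, at -2.69 (0.0586), and IFI44 also ended just short of the threshold (4.18, 0.0525).

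**Figure D2:**
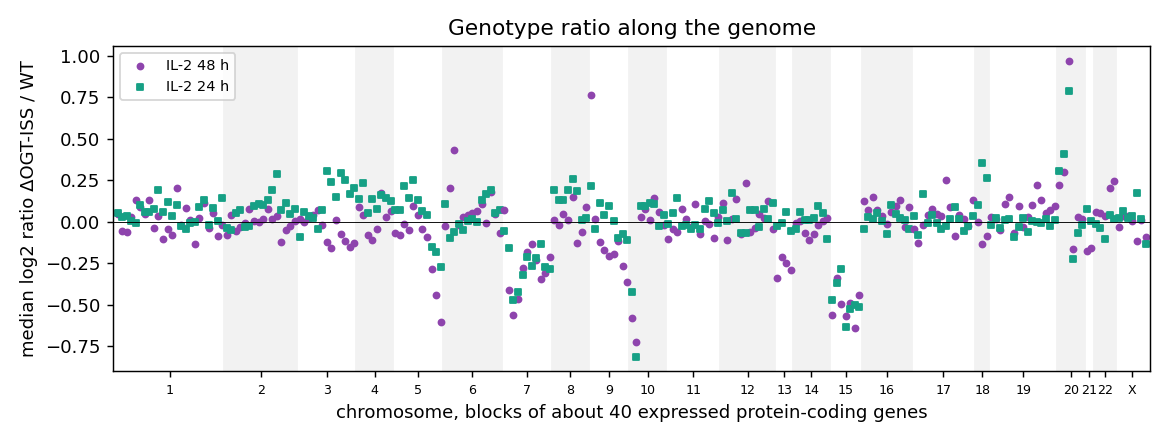
Median log2 ratio of ΔOGT-ISS to WT in blocks of about 40 neighbouring expressed protein-coding genes along the chromosomes (GRCh38), at 48 h and at 24 h. Chromosome 15 lies low in both pairs of libraries (-0.52 and -0.49), and a block of chromosome 20 lies high (0.97 and 0.78).

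Among the gene lists, type I interferon response genes were higher in ΔOGT-ISS. All 28 measured members had positive log2 values, with a median of 1.14 (camera adjusted p = 1.51e-12, adjusted p = 0.779 with an estimated correlation). Of these, IFI44L and IFI44 rose by the edgeR test, and 3 members passed adjusted over the list alone. The camera call held without each library in turn, but those fits also lacked the IL-2 term. They mix line with time and do not show that the line difference holds without a given library. The list's median log2 ratio was 2.59 at 48 h, and also with the 1 member at 0 counts set to its bound, but 0.01 at 24 h. Against 10000 random lists matched on mean expression these medians lay at percentiles 100 and 42.4, a description of single libraries. The difference between the times was not tested.

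The ATF4 and amino acid response list was also higher (median 0.43, camera adjusted p = 1.94e-05, adjusted p = 0.779 with an estimated correlation). Of its 19 measured members only SLC7A11, the cystine transporter, passed the edgeR test (log2 1.27, SE 0.18), and 3 passed adjusted over the list alone. Antigen presentation genes (median 0.22, camera adjusted p = 0.0279) and MYC and ribosome biogenesis genes (median 0.10, camera adjusted p = 0.0291) passed as higher with 0 members past the edgeR test over all genes or adjusted over the list alone. For both, adjusted p = 0.779 with an estimated correlation. The medians at 48 h and 24 h were 0.55 and 0.23 for ATF4, 0.62 and -0.12 for antigen presentation and -0.03 and 0.19 for MYC, and the SLC7A11 ratio was 2.69 (2.44 to 2.98) and 2.14 (1.80 to 2.54). With regional medians removed SLC7A11 ended short of the threshold (1.18, edgeR adjusted p = 0.0595). Without the IL-2 term and with all 4 libraries, 9 of the 10 lists named here still passed, and MYC did not (camera adjusted p = 0.126). The values that follow without 1 library, for these and the next lists, lack the IL-2 term too and mix line with time. Without ΔOGT-ISS replicate 1 the camera adjusted p was 0.182 for ATF4, 0.336 for antigen presentation and 0.804 for MYC. Without WT replicate 2 it was 0.903 for ATF4 and for MYC. Without ΔOGT-ISS replicate 2 it was 0.340 for antigen presentation and 0.583 for MYC, and without WT replicate 1 it was 0.744 for antigen presentation.

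Lists of NK effector and receptor genes were lower in ΔOGT-ISS. Of 16 cytotoxic granule genes 14 had negative values (median -0.47, camera adjusted p = 1.19e-06, adjusted p = 0.779 with an estimated correlation). The median was -0.08 at 48 h and -0.69 at 24 h, a difference that was not tested. Granzyme A (GZMA) fell by 1.26 log2 units (SE 0.19, edgeR adjusted p = 0.0479). It lies outside the shifted regions and with regional medians removed kept its size but ended short of the threshold (-1.26, SE 0.19, edgeR adjusted p = 0.0622). Granulysin (GNLY), at 49.1 CPM against 295 in WT at 24 h, did not pass (edgeR adjusted p = 0.288), and 2 members passed adjusted over the list alone. Among 18 activating receptors and adaptors (median -0.38, camera adjusted p = 1.85e-05, adjusted p = 0.779 with an estimated correlation), 3 fell and 6 passed adjusted over the list alone. These were the adhesion receptor CD2 (log2 -2.15, SE 0.22) and the signalling adaptors HCST (-1.55, SE 0.18) and TYROBP (-2.74, SE 0.34), adjacent genes on chromosome 19. The median of this list was -0.22 at 48 h and -0.55 at 24 h. Without WT replicate 2 the camera adjusted p was 0.389 for the granule genes and 0.0576 for the activating receptors.

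Inhibitory receptors were lower too (11 measured, median -0.14, camera adjusted p = 0.00154, adjusted p = 0.779 with an estimated correlation). HAVCR2, which encodes TIM-3, fell by 1.34 log2 units (SE 0.20, edgeR adjusted p = 0.0444), and 4 members passed adjusted over the list alone. HAVCR2 lies outside the shifted regions and with regional medians removed stood at -1.10 (SE 0.20, edgeR adjusted p = 0.113). The list's median was -0.11 at 48 h and -0.38 at 24 h. The cytokine and chemokine list (14 measured, median -0.49, camera adjusted p = 2.29e-05, adjusted p = 0.779 with an estimated correlation) had 0 members past the edgeR test over all genes and 3 adjusted over the list alone, with medians of -0.43 at 48 h and -0.35 at 24 h. XCL1 stood at -0.95 (SE 0.22) but has a near-identical copy, XCL2. Without ΔOGT-ISS replicate 2 the camera adjusted p was 0.0948 for the inhibitory receptors and 0.311 for the cytokines.

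The IL-2 and STAT5 response list was lower (21 measured, median -0.26, camera adjusted p = 0.0189, adjusted p = 0.779 with an estimated correlation). Its 1 member past the edgeR test, the transcription factor gene IRF4, went the other way and rose by 1.19 log2 units (SE 0.16), while IL2RA, in the chromosome 10 run, stood at -1.12 (SE 0.22). The list's median was -0.08 at 48 h and -0.34 at 24 h. Adjusted over the list alone, 2 members were higher and 4 lower, and without WT replicate 2 the list's camera adjusted p was 0.973. Myeloid markers, taken as genes of another cell type, were lower with 4 measured members (median -1.32, camera adjusted p = 6.01e-04, adjusted p = 0.779 with an estimated correlation). None of the 4 passed the edgeR test over all genes and 3 passed adjusted over the list alone, with medians of -0.64 at 48 h and -1.95 at 24 h. S100A9 stood at -1.65 (SE 0.51), and without ΔOGT-ISS replicate 2 the list's camera adjusted p was 0.597.

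The other 20 lists did not pass (camera adjusted p 0.0549 to 0.915). Of the lymphoid transcription factors, which had a median of 0.10, a mean of -0.16 and a downward camera direction, GATA3 (-1.42, SE 0.19) and IKZF1 (-1.01, SE 0.16) fell. They lie in the lower runs on chromosomes 10 and 7, and with regional medians removed they stood at -1.03 (edgeR adjusted p = 0.113) and -0.51 (0.461). Median and mean also differed in sign for G2/M genes (0.02 and -0.01), histones (0.02 and -0.17) and B cell markers (0.14 and -0.06), with an upward camera direction in each. For mitochondrially encoded genes they were -0.09 and 0.02, again with an upward direction. With fry, 0 of the 30 lists passed, with a lowest adjusted p of 0.144.

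**Figure D3:**
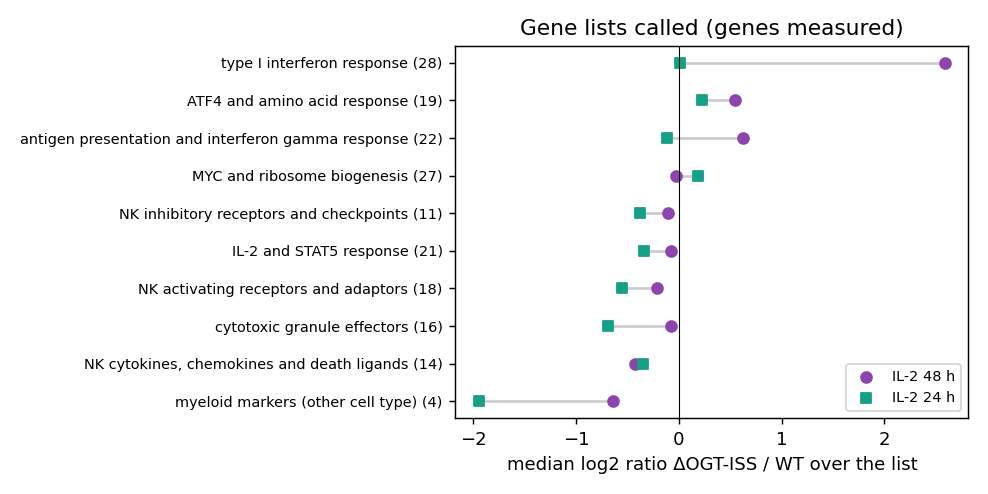
Median log2 ratio of ΔOGT-ISS to WT for the 10 gene lists that passed camera between the lines, at 48 h and 24 h, with the number of genes measured in brackets. The interferon list lies at 2.59 at 48 h and 0.01 at 24 h.

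The line difference was then set side by side at the 2 times. Across 9854 genes with a mean of at least 5 CPM, the log2 ratios at 48 h and 24 h correlated with r = 0.433 (rho = 0.326), and 59.7% of the genes had the same sign. These pairs share no library, and genes are not independent replicates. The ratios differed by over 2 log2 units for 116 of 9328 genes, lower at 24 h for 106 and higher for 10. IFI44L and the interferon-induced RSAD2 were among those lower at 24 h, with differences of -5.69 and -4.87, as was CPXM2, with 324 counts in WT and 3 in ΔOGT-ISS at 24 h (ratio 0.00786, 0.00161 to 0.0232). GCSAM lay higher at 24 h, with a ratio of 23.1 (13.0 to 45.1) against 2.67 at 48 h.

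**Figure D4:**
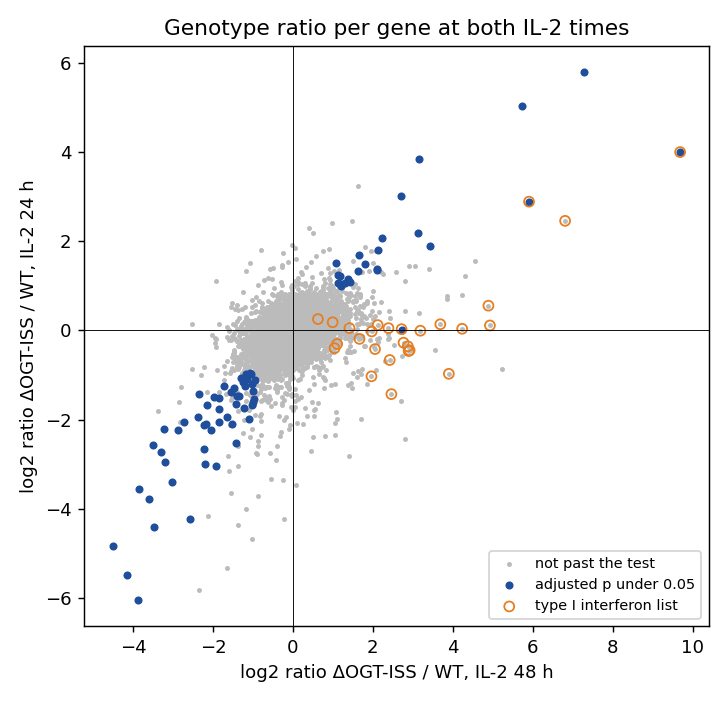
Log2 ratio of ΔOGT-ISS to WT at 48 h (x axis) and at 24 h (y axis) for 9854 genes with a mean of at least 5 CPM, from TMM-normalized CPM with a prior count of 2. The ratios correlate across genes with r = 0.433, and IFI44L lies farthest to the right, at 9.68 at 48 h.

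The IL-2 time separated the libraries more than the line did. At 24 h against 48 h, the surface glycoprotein gene CD52 rose from 2 to 522 counts over both lines, a ratio of 107 (29.5 to 886), and reached 2.52 CPM in ΔOGT-ISS and 18.2 CPM in WT. MGAT2, an N-glycan branching enzyme, had 4 and 0 counts in ΔOGT-ISS and WT at 48 h against 347 and 337 at 24 h. In WT this was at least 48.2-fold higher (interval from 39.0). For CD52 and MGAT2, a change in how reads were prepared or assigned between the times cannot be told apart from a rise in expression. The T and NK cell antigen CD7 rose 16.8-fold (log2 4.07, SE 0.43, edgeR adjusted p = 9.86e-04), and by 2.69 log2 units with offsets for GC content and length. ZNF683, which encodes the transcription factor HOBIT, stood at 3.64 (SE 0.81, edgeR adjusted p = 0.0150). It went from 3.31 to 138 CPM in WT and from 2.80 to 7.28 CPM in ΔOGT-ISS, and did not pass with the offsets (2.83, 0.0501), with DESeq2 (3.35, 0.0857) or without the line term (4.57, 0.0692). PDXP, ARRDC1, RHOF, ZNF296 and MEPCE rose by 4.01, 3.82, 3.70, 3.65 and 3.62, RHOF from 3 counts in WT at 48 h (ratio 49.8, 16.9 to 243). With the offsets these 5 stood at 2.76, 2.73, 2.75, 2.18 and 2.59. SNHG22 rose by 4.13, but it is annotated antisense to another gene and is uncertain.

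The chemokine gene CXCL8 showed the largest decrease among the named genes, with 158 and 338 counts at 48 h against 3 and 1 at 24 h (log2 -8.04, SE 0.52, edgeR adjusted p = 2.15e-04). The ratio was 0.00747 (0.00152 to 0.0222) in ΔOGT-ISS and 0.00127 (3.21e-05 to 0.00713) in WT. In ΔOGT-ISS, S100A12 and CTLA4 had 3 counts and 1 count at 24 h, ratios of 0.00472 (9.67e-04 to 0.0140) and 0.00447 (1.12e-04 to 0.0256). The myeloid receptor gene TREM1 fell by 5.92 log2 units (SE 0.36), and S100A12 had a log2 difference of -4.68 (SE 0.79). PFKFB4, a regulator of glycolysis, stood at -4.34 (SE 0.36; -5.0 with the offsets), PTPN3 at -3.87 (SE 0.43) and the inhibitory receptor gene CTLA4 at -4.21 (SE 0.77), all past the test. Without the line term PTPN3 and CTLA4 stood at -3.75 and -3.54 and did not pass (edgeR adjusted p = 0.157 and 0.113). The stress-induced factor gene ATF3 fell from 237 and 73 counts at 48 h to 25 and 17 at 24 h, in ΔOGT-ISS and WT. The ribosomal transcript MT-RNR1 fell by 4.52, in libraries that were depleted of ribosomal RNA. EIF5AL1 (-6.46) is a retrocopy and U2 (-4.03) a repeated small RNA gene, so both are uncertain.

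In all, edgeR called 4535 genes between the times, 2625 higher and 1910 lower at 24 h (57.9% higher), with 6784 at an unadjusted p of 0.05. Of the 4535 called, 2642 differed at least 2-fold and 4534 had the same sign in both lines, which again follows largely from the model. The differences followed GC content. Spearman's rho with GC was 0.472 over 16884 genes, and the median log2 difference ran from -0.42 at the low end of GC content to 1.11 at the high end. The 10 named higher genes had a median GC of 61.4% and the 10 lower ones 45.4%, against 47.9% for the genes tested. With offsets for GC and length, chosen after seeing the data, edgeR called 2061 genes, 1695 of them among the 4535, and 42.2% were higher. Of the named genes 9 higher and 10 lower ones were still called. Without the line term edgeR called 3280 genes, and leaving out 1 library as well gave 1306 calls without ΔOGT-ISS replicate 2 and 1098 without WT replicate 2.

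Replication-dependent histone genes were higher at 24 h, where 15 of 18 rose (16 adjusted over the list alone; median 1.18, camera adjusted p = 2.00e-10, adjusted p = 0.889 with an estimated correlation). H2BC5 rose by 2.53 log2 units (SE 0.20), H4C8 by 2.48 (SE 0.17) and H4C3 by 1.98 (SE 0.16), all members of families of similar copies. Genes of the unfolded protein response of the endoplasmic reticulum were lower, with 12 of 16 fallen (14 adjusted over the list alone; median -0.78, camera adjusted p = 2.91e-08, adjusted p = 0.889 with an estimated correlation). Among them DNAJB9 stood at -1.95 (SE 0.20), HERPUD1 at -1.84 (SE 0.20) and the chaperone gene HSPA5 at -1.22 (SE 0.17). Of 11 hypoxia genes 8 fell (9 adjusted over the list alone; median -1.55, camera adjusted p = 4.33e-06, adjusted p = 0.889 with an estimated correlation), with MXI1 at -3.22, P4HA1 at -2.90 and BNIP3L at -2.73.

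Of 19 ATF4 and amino acid response genes 11 fell and 1, ATF5, rose, and ATF5 went from 1.58 (SE 0.22) to 0.74 (SE 0.22, edgeR adjusted p = 0.0633) with the offsets (13 and 1 adjusted over the list alone; median -0.72, camera adjusted p = 1.77e-04, adjusted p = 0.889 with an estimated correlation). SLC7A11 fell by 2.85 log2 units (SE 0.19), and PSAT1, of serine synthesis, stood at -1.17 (SE 0.21). Of 16 NF-kB targets 9 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.95, camera adjusted p = 7.85e-04, adjusted p = 0.889 with an estimated correlation). BIRC3 fell by 2.93 (SE 0.17), and the feedback inhibitors TNFAIP3 and NFKBIA stood at -3.30 (SE 0.37) and -2.22 (SE 0.22). These 5 camera calls held without each library in turn, but those fits also lacked the line term. They mix time with line and do not show what a single library adds.

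Of 23 glycolysis genes 7 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.20, camera adjusted p = 0.0197, adjusted p = 0.889 with an estimated correlation), with HK2 at -1.23 (SE 0.16) and PDK1 at -1.62 (SE 0.20). Of 26 nuclear oxidative phosphorylation genes 11 fell and 1 rose, with the same counts adjusted over the list alone (median -0.37, camera adjusted p = 0.00601, adjusted p = 0.889 with an estimated correlation). Of 13 heat shock genes 5 fell (7 adjusted over the list alone; median -0.55, camera adjusted p = 0.00661, adjusted p = 0.889 with an estimated correlation), among them HSP90AA1 at -1.12 (SE 0.20). Of 13 mitochondrially encoded genes 3 fell (2 adjusted over the list alone; median -0.37, camera adjusted p = 0.0261, adjusted p = 0.889 with an estimated correlation), with MT-CO2 at -2.17 (SE 0.18). Without the line term and with all 4 libraries the camera adjusted p was 0.0619 for glycolysis and 0.0712 for mitochondrially encoded genes. Without WT replicate 1 as well it was 0.439 for glycolysis and for oxidative phosphorylation, 0.102 for heat shock and 0.0564 for mitochondrially encoded genes. For the mitochondrially encoded genes it was 0.227 without ΔOGT-ISS replicate 1, 0.0926 without ΔOGT-ISS replicate 2 and 0.526 with the GC and length offsets.

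The interferon list passed as lower at 24 h (5 of 28 fell and 1, BST2, rose, BST2 going from 0.94 to 0.39, edgeR adjusted p = 0.150, with the offsets, with the same counts adjusted over the list alone; median -0.69, camera adjusted p = 0.00105, adjusted p = 0.889 with an estimated correlation). Its median was 0.70 in WT and -2.18 in ΔOGT-ISS, a difference that was not tested. Without the line term it did not pass (camera adjusted p = 0.183). Without ΔOGT-ISS replicate 1 as well the list turned upward (camera adjusted p = 0.0255). It was 0.145 without ΔOGT-ISS replicate 2 and 0.0723 without WT replicate 2.

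The other 20 lists did not pass between the times (camera adjusted p 0.0681 to 0.955), and with fry 0 of 30 passed, with a lowest adjusted p of 0.348. Median and mean differed in sign for activating receptors (-0.06 and 0.05, upward direction), inhibitory receptors (0.21 and -0.10, downward), cytokines (0.09 and -0.46, downward), G2/M genes (-0.08 and 0.01, downward) and B cell markers (-0.11 and 1.44, downward). Myeloid markers had a median of -1.57 (camera adjusted p = 0.0681), and S100A9 fell by 2.66 log2 units (SE 0.52, edgeR adjusted p = 0.00920). Of the 8 measured T cell markers 4 rose (camera adjusted p = 0.0759), TRDC by 1.35 (SE 0.16), CD3E by 0.62 (SE 0.16), TRBC2 by 0.97 and CD6 by 2.06. With the offsets 3 of these 4 did not pass: CD3E, at about the same size (0.59, SE 0.17, edgeR adjusted p = 0.0598), TRBC2 (0.59, SE 0.17, 0.0677) and CD6 (1.03, SE 0.40, 0.130). Of 218 tested ribosomal protein pseudogenes 104 fell (median log2 -2.81), against a median of -0.59 for 80 ribosomal protein genes.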

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

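The tests of a swapped label, of low counts and of GC content and length in this part were all chosen only after the result was seen, with the bounds for GC set before that correction was run. Each result below had a difference between ΔOGT-ISS and WT in opposite directions at 48 h and 24 h, beyond counting error for the genes. With 1 library per line and time, the difference between the times was not tested.

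AP5B1 had log2 ratios of 1.41 at 48 h and -3.76 at 24 h, a difference of -5.17. CRNN had -1.93 and 1.10, a difference of 3.03. TC2N had -1.51 and 0.62, a difference of 2.13. The median of the MYC and ribosome biogenesis list was -0.03 at 48 h and 0.19 at 24 h, a difference of 0.21, but the 48 h value lies so near 0 that its sign says little. RSAD2, an antiviral interferon-induced gene, had log2 ratios of 3.90 at 48 h and -0.97 at 24 h, a difference of -4.87, and the antigen presentation list had medians of 0.62 and -0.12, a difference of -0.74.

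Whether the antigen presentation list and RSAD2 changed together was not tested. RSAD2 is a member of the interferon list, which lay at a median of 2.59 at 48 h and 0.01 at 24 h, and the checks below cover that list only. The values argue against a swapped genotype label in 1 of the pairs, since chromosome 15, although picked for its shift, lay low in both pairs (-0.49 in the pair nearer to 0). They also argue against low counts and GC content as the source: the 16 members with at least 100 counts in both 48 h libraries kept a median of 2.09, and after correction for GC and length the list median at 48 h was 2.46. IFI44L, IFI44 and IFI27, which had the largest ratios of the list at 48 h, also had more counts in ΔOGT-ISS at 24 h (121 against 4, 489 against 54 and 1833 against 282). From 48 h to 24 h the list median changed by 0.70 log2 units in WT and by -2.18 in ΔOGT-ISS, so the WT libraries differed too. An effect of the edit that depends on the time stays open for all members. So does a state of the cultures of either line, WT at 48 h included, which may have nothing to do with the edit.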

How the results depend on the processing

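The GC and length offsets, removal of regional medians, restriction to protein-coding genes and thinning were chosen only after the results were seen. The cause of a change was not tested unless stated. Between the lines, edgeR called 81 genes, against 154 with size factors from DESeq2, 546 without a filter, 303 with DESeq2's own test, 166 among protein-coding genes, 44 with the 24 h libraries thinned and 38 with regional medians removed. It called 0 without the IL-2 term (242 unadjusted), limma called 0 with either FPKM pseudocount (1340 and 1199 unadjusted), and leaving out 1 library, also without that term, gave 0 to 16. Other settings gave 81 to 96. Among these, library sizes without mitochondrial and abundant genes were followed by TMM, which brings the scaling back near that of the main fit. That setting therefore says little about abundant RNAs. Between the times edgeR called 4535 genes, against 2061 with the GC and length offsets and 1098 to 3657 without 1 library and the line term. Of the 2840 calls lost with the offsets, the median size fell from 0.95 to 0.43 log2 units with the SE at 0.19 in both, so smaller differences ended these calls. Other settings gave 3066 to 4897. The 10 lists called in each comparison became 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.779 and 0.144 between the lines, 0.889 and 0.348 between the times). Genes differing by over 2 log2 units between the times numbered 116, 127 with a prior count of 0.5 and 115 with size factors from DESeq2.

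For OGT the difference between the times, -0.02, was 0.19 without a filter, 0.17 with the offsets and -0.10 to 0.17 without 1 library. For OGA, 0.07 became -0.0085 with upper-quartile factors and -0.0494 to 0.29 without 1 library. Fits without 1 library lack the other factor, so a gene with a large difference between the times must swing between the lines, and these ranges do not measure how stable the line difference is. They gave, between the lines, -0.0492 to 3.96 for NRXN3, -7.92 to 0.73 for CTLA4, -7.19 to 7.13 for CXCL8, -0.79 to 3.19 for SLC7A11 and -3.78 to 0.0928 for S100A9, while within the times the NRXN3 ratio was 4.42 and 3.68 and the SLC7A11 ratio 2.69 and 2.14. Between the times they gave -7.91 to 8.55 for IFI44L. Among the named genes between the lines, 272 planned results kept direction and side of the threshold, 74 dropped below it and 13 passed it. In the fits without 1 library, 59 held and 99 dropped below. Between the times the planned results were 491 and 28, and 181 and 51 without 1 library. The main model is itself the paired analysis, since it pairs the lines within each time, and the labels carry no replicate numbers for a further block. Depth limits genes of low expression at 48 h, where a count of 0 allows up to 0.284 CPM in WT. The 48 h libraries also held few genes at a single count (0.973 and 0.932 for each gene at 2 counts, against 1.70 and 1.72 at 24 h and 2.02 and 1.99 there after thinning). Limits and intervals at low counts assume ordinary counting, which these values do not bear out at 48 h.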

Other observations

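The tests of copy number, of shuffled positions, of pseudogene reads, of GC content and length and of depth in this part were all chosen only after the result was seen, with the bounds for GC and depth set before those fits were run. Some lists that did not pass between the IL-2 times held members that did. Of the 21 IL-2 and STAT5 response genes 7 rose and 4 fell at 24 h (camera adjusted p = 0.298), and the list median of 0.23 became -0.18 with the GC and length offsets. Its members CISH and PIM1 rose by 1.60 and 1.33 log2 units (SE 0.16 each), and by 0.98 and 0.75 with the offsets. As the offsets also remove real differences that follow GC content, a call lost with them does not mark a gene as an artifact. Of the 16 granule genes 4 rose and 1 fell (median 0.0030, camera adjusted p = 0.561), with GZMM at 3.01 (SE 0.31; 1.66 with the offsets). Of the 14 cytokine and chemokine genes 5 rose and 4 fell (camera adjusted p = 0.955): TNF rose by 1.89 (SE 0.20), while IFNG fell by 1.73 (SE 0.20) and CCL4, which has a similar copy, fell by 1.57 (SE 0.19). Of the 20 lymphoid transcription factors 7 rose and 3 fell (camera adjusted p = 0.561), with NFIL3 down at -1.95 (SE 0.16). With the offsets IL2RB, UNC13D, NCR3 and TBX21, which had differences of 0.98, 1.60, 1.07 and 1.02 (SE 0.16, 0.17, 0.16 and 0.19), stood at 0.27, 0.49, 0.47 and 0.17 (SE 0.18, 0.18, 0.17 and 0.21) and did not pass (edgeR adjusted p = 0.353, 0.117, 0.108 and 0.655).

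The regional shift on chromosomes 7, 10, 15 and 20 invites a comparison with copy number, for which no DNA measurement was used here. The values argue against GC content and length as its source, since the corrected chromosome 15 median stayed at -0.49 at the time nearer to 0. After the same correction the run on chromosome 7 lay at -0.54 at 48 h and -0.43 at 24 h. The run on chromosome 10 lay at -0.67 and -0.68, and that on chromosome 20 at 0.87 and 0.81. The values for chromosome 15 also argue against a chance arrangement of changed genes. Of 1000 shufflings of gene positions, 0 gave a chromosome median as far from 0 as 0.493, and their largest was 0.112. The shuffling used only the largest median of a whole chromosome, so it does not cover the runs on the other chromosomes. The share of chromosome 15 genes below the genome median, looked at first, was set aside because that chromosome had been picked for its shift. Instead, 21 blocks were picked on the 48 h pair alone. Of these, 11 (52.4%) passed the same size and sign in the 24 h pair, between the bounds set for and against. Of all 227 blocks, 16 passed 0.3 log2 units in either direction at 24 h. The shifts thus recurred between the pairs more often than that share alone would give. Blocks that missed the size mostly kept their sign, such as chromosome 15 from 43804492 to 55355648 (-0.50 and -0.29). Chromosome 6 from 26402237 to 30070333 did not (0.43 and -0.06). Some shifts were larger at 48 h, as on chromosome 9 from 121038 to 26892804 (0.76 and 0.22). The same held on chromosome 5 from 176526697 to 181261139 (-0.60 and -0.28). The median of chromosome 13 was -0.29 at 48 h and -0.0082 at 24 h. These differences between the times were not tested. A copy number difference between the lines may therefore underlie some regions, and cannot be told apart from regional regulation with expression alone.

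The number of genes called between the IL-2 times may partly reflect how the libraries were made. With GC and length offsets edgeR called 2061 genes against 4535 (45.5%), just past the bound set for it. GC content and length thus remain a candidate source of part of the calls. The offsets also remove a response to IL-2 that follows GC content. The fall in calls therefore cannot tell a technical trend from a biological one. For the ribosomal protein pseudogenes, reads shared with parent genes remain a candidate source that these values do not settle. Their median lay -2.22 log2 units from that of the ribosomal protein genes, but this gap restates their fall and does not show where reads went. The 80 ribosomal protein genes fell too, with 41 called lower and 4 higher. For the 682 other processed pseudogenes, with a median of -0.33 and 124 called lower, no such comparison was made. Depth is not the main source, since with the 24 h libraries thinned edgeR called 4415 genes, of which 4173 were among the 4535 (92.0%). The IL-2 time itself stays open as a source and is fully confounded with any difference in preparation between the 48 h and 24 h libraries.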
